A study of Caenorhabditis elegans with 20 samples.

How the data were processed

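RNA from whole adult *Caenorhabditis elegans* was measured on 20 Affymetrix whole-genome arrays, 5 biological replicates of each of 4 genotypes. Per the labels, scanner images were converted in Microarray Suite (MAS) 5.0, and the Robust Multi-chip Average (RMA) was run jointly on the 20 arrays, in R, with version 1.4.14 of its package for Affymetrix arrays. The deposited values are on the log2 scale, which was read from their range and not from a label. Quantile normalization is part of this method as usually run, and it gives arrays similar distributions, so a change in the total amount of RNA would not be seen. The scanner images were not analysed here, and no value on whether a probe set was detected is given in the sources used here. Signal over background was therefore judged from the 15 Bacillus control probe sets for dap, lys and trp, and no other Bacillus controls were used.

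The table held 22625 probe sets, of which 77 Affymetrix control probe sets were left out of the tests and 22548 were tested. Per the array annotation used here, 20766 of these had 1 gene symbol, 887 had several and 895 had none. No gene was named from a probe set with several symbols. By gene identifier, 20701 symbols were matched to a table of RefSeq genes on assembly WBcel235, which was used only for names and for the order of genes along chromosomes. The assembly behind the array design is not given in the sources used here, so no coordinates are printed. For each of 17118 genes, the probe set with the highest mean over all 20 arrays stood for the gene in the lists.

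Groups were taken from the genotypes in the labels. A linear model with 1 mean per genotype was fitted to all 20 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), with no covariates. It gave 6 comparisons: the *daf-16* difference over both *daf-2* alleles, in e1370 and in m577, the difference between these differences, and the alleles compared with and without *daf-16*. Differences for *daf-16* are *daf-2* minus *daf-16*; *daf-2*, and differences between alleles are e1370 minus m577. All tests were 2-sided. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Adjusted p-values without another test's name are from limma. Figures were drawn with matplotlib 3.10.9.

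The tests and the 46 gene lists were fixed before the data were examined, as were the first group of other settings below and the rule for the genes named. Lists were tested with camera from limma at a preset correlation between genes of 0.01, adjusted over the 46 lists within a comparison, and again with the correlation estimated for each list. Lists needed at least 3 measured genes. Members past the threshold were counted over all probe sets and when adjusted over the list alone. Mean levels per array were compared between genotypes by exact permutation of 5 against 5 arrays, adjusted over 60 tests.

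By the naming rule, *daf-16*, *daf-2* and *glp-4* were reported in every genotype. Each comparison gave the 10 genes with the largest rise and the 10 with the largest fall, or 6 and 6 between alleles. These had 1 symbol, an adjusted p under 0.05 and no overlap between the arrays compared, in both alleles for the mean comparison, while the test of the difference between differences did not ask for this. Each list described gave up to 4 members with the largest change past the threshold, or the 2 largest where none passed, and 4 short lists could be named in full.

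The first group of other settings was centring each array on its median, cyclic loess, leaving out dim probe sets, an intensity trend with robust settings, array quality weights, a fit of only the genotypes compared, 1 probe set per gene, a test against a 1.2-fold change, a block for the replicate number, a block for the number in each alternative sample name, and leaving out each of the 20 arrays. For lists they also included the estimated correlation and the mean over all probe sets of a gene. After the data were seen, 3 more were added: the oocyte and sperm gene means as covariates, the 3' minus 5' difference of control transcripts as a covariate, and leaving out the array of each genotype that correlated least with the others. For other splits of the arrays, 100 were drawn for each comparison. Correlations across arrays were tested with 100000 permutations.

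The model was tested on simulated data with the means and spreads of the 22548 probe sets and 50 changed probe sets for each size. The noise was drawn independently for each probe set. Deviations shared by many probe sets, which the real arrays have, were absent, so the shares do not cover them. For the *daf-16* difference over both alleles, 72% of changes of 1 on the log2 scale and 94% of changes of 2 were recovered. The shares were 62% and 86% in e1370, 54% and 84% in m577, and 36% and 68% for the difference between differences. Between alleles they were 56% and 92% with *daf-16* and 46% and 94% without it. Unchanged probe sets made up 13 of 164 calls over both alleles, 9 of 147 in e1370 and 5 of 133 in m577. They made up 10 of 107 for the difference between differences, and between alleles 7 of 134 with *daf-16* and 11 of 141 without it.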

Results

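Gene expression was measured in whole adult *Caenorhabditis elegans* on 20 Affymetrix whole-genome arrays, 5 for each of 4 genotypes. The genotypes joined either of 2 alleles of *daf-2*, e1370 or m577, with the presence of *daf-16* or its loss through mgDf50. *daf-2* encodes the insulin/IGF-1 receptor, and *daf-16* encodes the FOXO transcription factor that signalling from this receptor holds out of the nucleus. Every strain also carried *glp-4*(bn2), a temperature-sensitive mutation under which few germ cells form at the restrictive temperature. Per the labels, larvae were grown at 15 °C and moved to 25 °C at about the L4 stage, and RNA came from sterile adults aged 1 day, with 8 plates making up each biological replicate. Values are on the log2 scale, with array medians from 6.41 to 6.57, and differences are given with their standard error (SE) for 5 arrays per genotype. The 15 Bacillus control probe sets for dap, lys and trp, which match no worm gene, had a median level of 4.57 (range 4.21 to 6.29), and this was taken as the background level. Of 211 called values of named genes, 79 had at least 1 compared genotype with a mean no higher than 6.29. The sizes of those differences are limited by background, so their order is uncertain. The number of arrays limits the precision of every comparison.

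Arrays of a genotype were not equally alike. The lowest correlation between a pair of arrays, taken across probe sets, which are not independent replicates, was 0.785 in *daf-16*(mgDf50); *daf-2*(e1370) and 0.853 in *daf-2*(e1370). It was 0.879 in *daf-2*(m577) and 0.956 in *daf-16*(mgDf50); *daf-2*(m577). Genes of germ cells and oocytes had mean levels from 7.84 to 10.65 over the 20 arrays, and genes of sperm from 7.80 to 11.43. Sperm gene levels were lowest on replicate 3 of *daf-2*(m577) (7.80), replicate 5 of *daf-16*(mgDf50); *daf-2*(e1370) (7.81) and replicate 4 of *daf-2*(e1370) (8.51), where the oocyte gene levels were 10.34, 10.42 and 10.33. On the other 17 arrays the sperm gene level was at least 9.61.

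**Figure D1:**
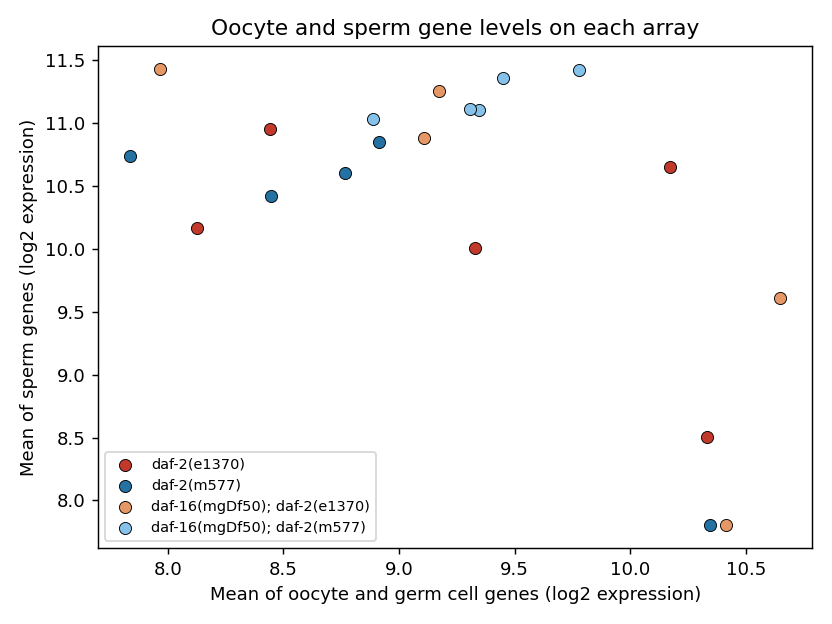
Mean log2 level of the 42 oocyte and germ cell genes (x axis) against that of the 48 sperm genes (y axis) on each of the 20 arrays, with 1 point per array and a colour for each genotype. The 5 arrays of *daf-16*(mgDf50); *daf-2*(m577) lie close together, with a mean sperm gene level of 11.21, while the level fell as low as 7.80 on 1 array of *daf-2*(m577) and 7.81 on 1 array of *daf-16*(mgDf50); *daf-2*(e1370).

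*daf-16* itself is covered by 4 probe sets. The levels of probe set 175678_at were 6.97 ± 0.50 in *daf-2*(e1370), 6.98 ± 0.18 in *daf-2*(m577), 5.99 ± 0.62 in *daf-16*(mgDf50); *daf-2*(e1370) and 6.43 ± 0.31 in *daf-16*(mgDf50); *daf-2*(m577) (SD, n = 5). With *daf-16* present it was higher by 0.76 ± 0.19 over both alleles (limma adjusted p = 0.0174), and probe set 181992_s_at was higher by 0.69 ± 0.17 (adjusted p = 0.0175), with all 4 genotype means inside the background range. The remaining *daf-16* probe sets, 175823_s_at and 188176_s_at, differed by 0.07 ± 0.27 and 0.38 ± 0.25 (adjusted p = 0.93 and 0.528). Which of these probe sets lie inside the part deleted by mgDf50 is not given in the sources used here, and a probe set outside that part does not test the genotype. The 4 probe sets of *daf-2* had genotype means from 4.75 to 5.48, close to background, and none of them passed the threshold in any of the 6 comparisons. *glp-4* was lower with *daf-16* present, by -0.98 ± 0.27 over both alleles (adjusted p = 0.0352).

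The first comparison asked which transcripts depended on *daf-16* in animals with reduced *daf-2* function, as the mean of the difference in both alleles. *ftn-1*, which encodes a ferritin that stores iron, was higher with *daf-16* present by 5.20 ± 0.16, a 36.7-fold difference. *sod-3*, a mitochondrial superoxide dismutase, was higher by 4.16 ± 0.18, and its level was 11.91 ± 0.24 in *daf-2*(e1370) against 7.16 ± 0.49 in *daf-16*(mgDf50); *daf-2*(e1370) (SD, n = 5). The uncharacterised gene *D1086.9* had the largest rise, 5.76 ± 0.27, followed after *ftn-1* by *F15B9.6* (5.13 ± 0.32) and *scl-20*, which encodes a secreted SCP-like protein (4.44 ± 0.31). *H39E23.3*, *dod-6*, the C-type lectin *clec-61*, the transthyretin-like *ttr-26* and the claudin-like *clc-24* rose by 3.86 to 4.19. In the other direction, *C32H11.4* fell by 4.23 ± 0.27 and *dod-24* by 3.71 ± 0.24, and the aspartyl protease *asp-17*, the O-acyltransferase homologues *oac-6* and *oac-20*, *irg-8*, *C40H1.7*, *dod-22*, *endu-2* and *sdz-6* fell by 3.16 to 3.44. In 10 of these 20 genes, *D1086.9*, *F15B9.6*, *scl-20*, *ttr-26*, *C32H11.4*, *oac-6*, *oac-20*, *C40H1.7*, *dod-22* and *sdz-6*, the mean of at least 1 genotype lay inside the background range. Arrays with and without *daf-16* that did not overlap in both alleles were a condition for naming these 20 genes, so this is no further evidence for them.

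Of 22548 probe sets, 1425 differed (limma, adjusted p under 0.05), 818 higher and 607 lower with *daf-16* present, and they covered 1137 of 17118 genes. At least a 2-fold difference was seen in 359 of those that rose and 319 of those that fell. The count was 643 with the 3' minus 5' difference of control transcripts as a covariate, 649 in a test against a 1.2-fold change, 699 (488 higher and 211 lower) with a block for the number in the alternative sample names and 3390 with array quality weights.

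Among the fixed gene lists, the list of genes reported elsewhere as raised in *daf-2* mutants through *daf-16* held 24 measured genes, of which 14 rose and 1 fell, and 15 rose and 1 fell when adjusted over the list alone (camera adjusted p = 1.38e-20, and adjusted p = 0.00139 with an estimated correlation). Besides the genes above, the metallothionein *mtl-1* (3.45 ± 0.31), the small heat shock proteins *hsp-12.3* (3.60 ± 0.26) and *hsp-12.6* (2.01 ± 0.38) and the transhydrogenase *nnt-1* (3.43 ± 0.15) rose, while the fatty acid desaturase *fat-7* fell by 0.93 ± 0.15. The list of genes reported elsewhere as lowered held 9 genes, of which 6 fell, 7 when adjusted over the list alone (camera adjusted p = 4.01e-15, and adjusted p = 7.23e-05 with an estimated correlation). *ins-7*, an insulin-like peptide, fell by 2.54 ± 0.39. Both lists were drawn from published work that may include these arrays, so they are not independent evidence of direction. Of the 9 superoxide dismutases, catalases and peroxiredoxins, *sod-3*, *sod-5* (1.67 ± 0.29) and *sod-1* (0.81 ± 0.09) rose and none fell, and 4 rose when adjusted over the list alone (camera adjusted p = 1.95e-05, and adjusted p = 0.00552 with an estimated correlation). *sod-2* differed by 0.37 ± 0.14 and the *ctl-2* probe set in the list by 0.32 ± 0.22, below the threshold. The 3 catalase control probe sets of the array, which are outside the list, were higher by 4.30-fold to 5.42-fold (limma, adjusted p = 7.73e-07 or less over 15 control probe sets), and these sizes are limited by background, since their means in *daf-16*(mgDf50); *daf-2*(m577) were 5.57 to 6.25. Probe set 188587_s_at, annotated to 2 genes and also outside the list, rose by 2.67 ± 0.26 (adjusted p = 1.29e-06).

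Enzymes that modify foreign compounds moved in both directions. Of 74 cytochrome P450 genes 17 rose and 7 fell, 20 and 8 when adjusted over the list alone, and the list was shifted upwards (camera adjusted p = 0.00501, but adjusted p = 0.703 with an estimated correlation). *cyp-35B1* rose by 3.23 ± 0.25 and *cyp-35A3* fell by 1.59 ± 0.31. Among 45 glutathione S-transferases 10 rose and 3 fell, 19 and 4 when adjusted over the list alone (camera adjusted p = 0.00166, adjusted p = 0.703 with an estimated correlation), with *gst-29* up by 2.13 ± 0.20 and *gst-38* down, at -2.49 ± 0.30. Of 64 UDP-glucuronosyltransferases 7 rose, 16 fell and 41 did not pass, 9 and 20 changed when adjusted over the list alone, and the list's shift did not pass (median -0.02, camera adjusted p = 0.145).

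Of the 7 genes of the glyoxylate cycle and gluconeogenesis 4 rose, also 4 when adjusted over the list alone (camera adjusted p = 0.00227, adjusted p = 0.671 with an estimated correlation), among them the isocitrate lyase gene *icl-1* (1.65 ± 0.40) and *pck-1*, which encodes phosphoenolpyruvate carboxykinase (1.57 ± 0.31). Lipases and lipid carriers had 7 of 44 genes higher and 4 lower, the same numbers when adjusted over the list alone (camera adjusted p = 0.0305, adjusted p = 0.703 with an estimated correlation). The lysosomal lipase *lipl-4* rose by 2.44 ± 0.18, and the fatty acid binding protein *lbp-7* fell by 2.33 ± 0.39. The list of the insulin pathway held 11 measured genes, with *daf-2* and *daf-16* itself among them. The kinase genes *akt-2* (1.88 ± 0.21), *akt-1* (1.30 ± 0.25) and *pdk-1* (1.14 ± 0.23) rose and *sgk-1* fell by 0.94 ± 0.22. The probe sets of *pdk-1* did not move alike. In e1370 those that differed by 1.22 and 0.97 passed the threshold, while those that differed by -0.03, 0.15 and 0.27 did not. In total 4 of the 11 rose and 1 fell, likewise when adjusted over the list alone (camera adjusted p = 0.0859).

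Of 19 intestinal genes 9 fell and 1 rose with *daf-16* present, 11 and 1 when adjusted over the list alone (camera adjusted p = 5.99e-08, but adjusted p = 0.468 with an estimated correlation). *pept-1*, the intestinal peptide transporter, fell by 2.95 ± 0.31, the acid phosphatase *pho-1* by 2.54 ± 0.23 and the sodium-proton exchanger *nhx-2* by 2.48 ± 0.29, whereas the gut esterase *ges-1* rose by 1.88 ± 0.23. Of 220 C-type lectins 6 rose and 22 fell, 7 and 27 when adjusted over the list alone, with a median of 0.07, a mean of -0.04 and no shift of the list (camera adjusted p = 0.966). Of 18 saposin-like genes 5 rose and none fell, 8 rose when adjusted over the list alone (camera adjusted p = 0.00125, adjusted p = 0.671 with an estimated correlation), led by *spp-13* (2.49 ± 0.22). Sperm genes had a median of -0.66, with 1 of 48 lower and the same when adjusted over the list alone (camera adjusted p = 1.95e-05, adjusted p = 0.703 with an estimated correlation). This median was -0.42 without replicate 4 of *daf-2*(e1370), -0.35 without replicate 3 of *daf-2*(m577) and -0.999 without replicate 5 of *daf-16*(mgDf50); *daf-2*(e1370). None of the 42 oocyte and germ cell genes passed the threshold, either over all probe sets or adjusted over the list alone (median -0.33, camera adjusted p = 0.00501, adjusted p = 0.749 with an estimated correlation). The call of that list was lost without replicate 1 of *daf-2*(e1370), replicate 1 of *daf-2*(m577), or replicate 3 or 5 of *daf-16*(mgDf50); *daf-2*(e1370), with medians from -0.22 to -0.20, and the median was -0.52 without replicate 3 of *daf-2*(m577).

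**Figure D2:**
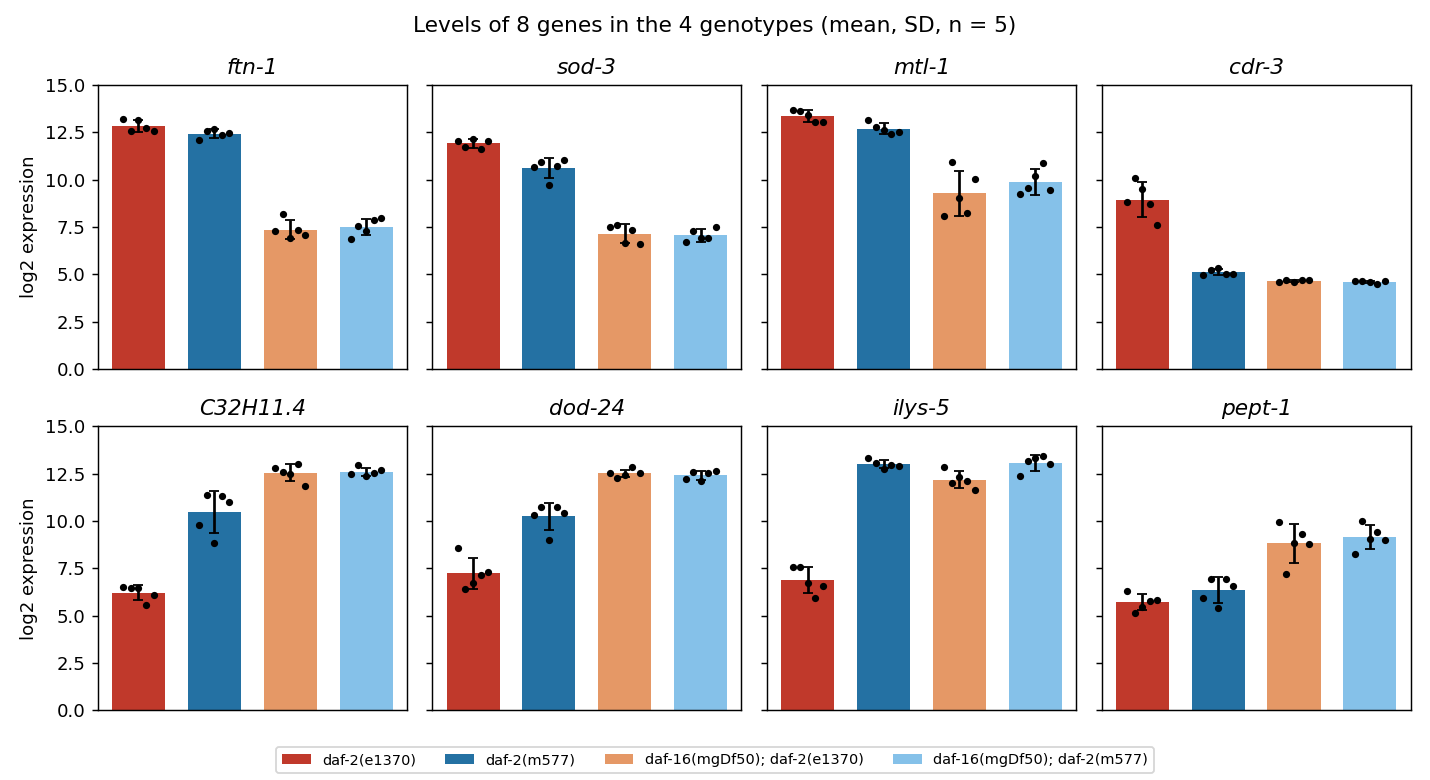
Log2 levels of 8 named genes on each array (points), with the mean of each genotype (bar) and its SD (error bar, n = 5). *ftn-1* and *sod-3* were higher in both genotypes with *daf-16*, *C32H11.4* and *dod-24* were lower, and *ilys-5* was low, at 6.88, only in *daf-2*(e1370).

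In *daf-2*(e1370) alone, *D1086.9* was higher with *daf-16* present by 6.73 ± 0.38 and *ftn-1* by 5.47 ± 0.23. The cuticle collagen gene *col-183* (4.81 ± 0.52), *K03D3.2* (4.79 ± 0.33), *sod-3* (4.75 ± 0.25) and *hsp-12.3* (4.49 ± 0.37) were also among the 10 largest rises. The deepest fall was in *C32H11.4*, by 6.32 ± 0.39. It was followed by *ilys-5*, an invertebrate-type lysozyme, which fell by 5.30 ± 0.29, and by *dod-24*, *irg-8* and *irg-5*, which fell by 4.37 to 5.27. Of 57 called values of named genes in this allele, 25 had a genotype mean inside the background range, those of *D1086.9*, *col-183*, *K03D3.2* and *C32H11.4* among them. In this allele 987 probe sets differed (limma), 541 higher and 446 lower, from 824 genes. The arrays of the 2 genotypes did not overlap for 852 probe sets, against a chance share of 0.794% for 5 arrays against 5, and 685 of these were among the 987. The count was 507 when only these 2 genotypes were fitted and 616 in the test against a 1.2-fold change.

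Of the intestinal genes 8 fell and 1 rose in this allele, 12 and 1 when adjusted over the list alone (camera adjusted p = 2.08e-10, adjusted p = 0.194 with an estimated correlation). The mean level of the list was 8.39 ± 0.23 in *daf-2*(e1370) and 9.48 ± 0.54 in *daf-16*(mgDf50); *daf-2*(e1370) (SD, n = 5, exact permutation test, 2-sided, p = 0.00794, the smallest that 5 against 5 allows, adjusted p = 0.0595 over 60 such tests). Saposin-like genes had 4 of 18 higher and none lower, 10 when adjusted over the list alone (camera adjusted p = 1.04e-06, adjusted p = 0.194 with an estimated correlation). C-type lectins had 4 of 220 higher and 21 lower, 5 and 28 when adjusted over the list alone (camera adjusted p = 0.0155, adjusted p = 0.799 with an estimated correlation). *clec-265* fell by 4.00 ± 0.50 while *clec-61* rose by 4.33 ± 0.50. In the list of ATP-binding cassette transporters, *pgp-5*, *haf-6* and *pgp-8* fell out of 29 genes, by 0.69 to 2.31, and none rose (1 higher and 4 lower when adjusted over the list alone, camera adjusted p = 0.000759, adjusted p = 0.497 with an estimated correlation). Both means of *pgp-8* lay inside the background range.

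In *daf-2*(m577), *F15B9.6* (5.40 ± 0.45), *ftn-1* (4.92 ± 0.23) and *D1086.9* (4.79 ± 0.38) led the rises, followed by *H39E23.3* and *scl-20*. *nnt-1*, *hen-1*, *sod-3*, *clec-61* and *dod-6* rose by 3.28 to 3.91. The largest falls were in the claudin-like gene *clc-19* (-3.38 ± 0.42), *oac-20* (-3.30 ± 0.29), *endu-2* (-3.27 ± 0.41) and the acid phosphatase *pho-8* (-3.22 ± 0.45), and *pept-1* fell by 2.79 ± 0.43. A mean inside the background range went into 10 of 35 called values of named genes, among them those of *F15B9.6*, *D1086.9*, *scl-20*, *hen-1*, *oac-20* and *pho-8*. Here 404 probe sets differed (limma), 270 higher and 134 lower, from 322 genes. For 1502 probe sets the arrays of the 2 genotypes did not overlap, against the chance share of 0.794%, and 373 of these were among the 404.

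The mean 3' minus 5' difference of the actin, GAPDH and ubiquitin control probe sets, taken as a measure of RNA integrity, was 1.33 ± 0.16 in *daf-2*(m577) and 1.87 ± 0.25 in *daf-16*(mgDf50); *daf-2*(m577) (SD, n = 5, exact permutation test, 2-sided, p = 0.00794, the smallest possible, adjusted p = 0.0595 over 60 tests). Sperm genes had a mean level of 10.08 ± 1.29 against 11.21 ± 0.17 (same test, p = 0.00794, adjusted p = 0.0595), and the list shifted downwards (median -1.18, 1 of 48 lower, also when adjusted over the list alone, camera adjusted p = 4.06e-10, adjusted p = 0.649 with an estimated correlation). Without replicate 3 of *daf-2*(m577) the difference in mean level went from -1.12 to -0.55, and the median of the list to -0.49. The list of cytosolic ribosomal protein genes had a median of -0.17 (78 genes, none past the threshold over all probe sets or over the list alone, camera adjusted p = 6.68e-12, adjusted p = 0.611 with an estimated correlation). All 3 GAPDH control probe sets rose with *daf-16* over both alleles, by 1.47-fold to 1.96-fold (limma, adjusted p = 0.0134 or less over 15 controls). In m577 the 5' one rose by 0.94 and the 3' one by 0.34. The GAPDH part of the score therefore cannot tell RNA integrity from a change in these transcripts. Between the m577 genotypes this part differed by -0.60, the actin part by -0.45 and the ubiquitin part by -0.57. The count of 404 was 58 with the 3' minus 5' difference as a covariate, 105 with the block for the alternative sample names, 180 in the test against a 1.2-fold change, 672 without the least typical array of each genotype, 780 with only these genotypes and 6645 with array quality weights. It was 257 without replicate 3 and 266 without replicate 4 of *daf-16*(mgDf50); *daf-2*(m577).

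The differences in the 2 alleles, which share no arrays, could be set side by side. Across all probe sets their correlation was 0.558, a value across genes, which are not independent replicates. Over all 22548 probe sets 61.3% had the same sign in both alleles. Among the 1425 called over both alleles the share was 99.1%, but these were selected on the mean of both differences, which favours a shared sign, and 71.7% had the larger difference in e1370, with median sizes of 1.14 in e1370 and 0.76 in m577. Over all probe sets the order was the opposite, with 39.2% larger in e1370 and median sizes of 0.13 in e1370 and 0.20 in m577. The probe sets called higher in both alleles numbered 172, against 6.48 for independent lists, and those called lower 103, against 2.65. None was called in opposite directions.

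**Figure D3:**
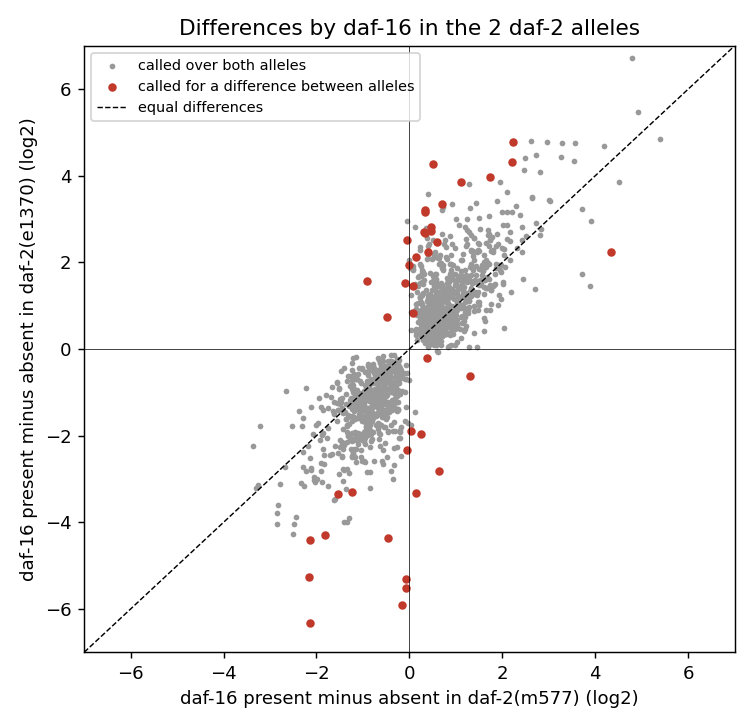
The log2 difference between arrays with and without *daf-16* in *daf-2*(m577) (x axis) and in *daf-2*(e1370) (y axis), for the 1425 probe sets called over both alleles (grey) and the 40 called for a difference between the alleles (red, drawn over grey where a probe set was called in both tests). The dashed line marks equal differences. Of the 1425 probe sets, 71.7% had the larger difference in e1370, against 39.2% of all 22548 probe sets, most of which are not drawn.

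The test of whether the *daf-16* difference itself depended on the *daf-2* allele singled out *ilys-5* most clearly. Its level was 6.88 ± 0.70 in *daf-2*(e1370) (SD, n = 5), while the means of the other 3 genotypes were 12.18 to 13.06 with SDs of 0.22 to 0.45, so that the difference of differences was -5.24 ± 0.41 (limma adjusted p = 1.63e-06). *C32H11.4* (-4.18 ± 0.55), *irg-5* (-3.92 ± 0.49), *C17H12.8* (-3.46 ± 0.44) and *dod-24* (-3.12 ± 0.49) also had negative values, as did *C17H12.6*, *W04A4.2*, *irg-8*, *drd-50* and *fat-7*, from -2.47 to -1.91. All of these fell in e1370, whereas in m577 *C32H11.4*, *dod-24*, *C17H12.6*, *irg-8* and *drd-50* fell and the others did not pass, with differences of -0.45 for *irg-5*, -0.07 for *ilys-5*, -0.04 for *W04A4.2*, 0.03 for *fat-7* and 0.64 for *C17H12.8*. *cdr-3*, from a family responsive to cadmium, was higher in *daf-2*(e1370), at 8.95 ± 0.92, than in the other genotypes, whose means of 4.61 to 5.12 lay inside the background range, and its value was 3.78 ± 0.40. *F40G12.5* (2.88 ± 0.39), *far-7*, a fatty acid and retinol binding protein (2.82 ± 0.53), *dod-3* (2.74 ± 0.50) and *gst-3* (2.65 ± 0.38) followed, and *K03D3.2*, *F53A9.1*, *cyp-13B1*, *piit-1* and *djr-1.2* had values from 2.35 to 2.56. For *F40G12.5* and *djr-1.2* the same 3 genotypes lay inside the background range, and so did at least 1 genotype for *far-7*, *gst-3*, *K03D3.2*, *cyp-13B1*, *C32H11.4* and *C17H12.6*, so the order of these genes is uncertain.

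In all, 40 probe sets differed in this test, 22 with a positive and 18 with a negative value, and in 37 of them the difference was larger in e1370. In 11 of the 40 it had opposite signs in the 2 alleles. After cyclic loess the split was 17 positive and 25 negative. Of the list of genes reported elsewhere as lowered in *daf-2* mutants, *dod-24* and *dod-23* (-1.80 ± 0.32) fell further in e1370, also 2 of 9 when adjusted over the list alone (camera adjusted p = 3.58e-06, adjusted p = 0.0154 with an estimated correlation). Among the glutathione S-transferases *gst-3*, *gst-41* (1.94 ± 0.38) and *gst-15* (1.87 ± 0.28) had positive values out of 45, also 3 when adjusted over the list alone (camera adjusted p = 0.0209, adjusted p = 0.8 with an estimated correlation). The count was 6 with the block for the alternative sample names, 16 with the 3' minus 5' difference as a covariate, 24 in the test against a 1.2-fold change, 120 with the oocyte and sperm scores as covariates and 1113 with array quality weights. Leaving out 1 array gave 71 without replicate 5 of *daf-2*(e1370), 67 without replicate 2 of *daf-16*(mgDf50); *daf-2*(e1370), 25 without its replicate 3 or its replicate 4, 25 and 26 without replicates 4 and 5 of *daf-2*(m577), and 24, 24 and 26 without replicates 2, 3 and 4 of *daf-16*(mgDf50); *daf-2*(m577).

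Between the 2 *daf-2* alleles with *daf-16* present, *ilys-5* was lower in e1370 than in m577 by -6.12 ± 0.29 and *C32H11.4* by -4.23 ± 0.39. *irg-5* (-3.78 ± 0.35), *C17H12.8* (-3.45 ± 0.31), *bcf-1* (-3.16 ± 0.63) and *dod-24* (-3.02 ± 0.34) were also lower. *cdr-3* was higher in e1370 by 3.83 ± 0.29, *F40G12.5* by 2.85 ± 0.28, *gst-3* by 2.76 ± 0.27 and *K03D3.2* by 2.58 ± 0.33. The means of *cdr-3* and *F40G12.5* in *daf-2*(m577), 5.12 and 5.00, lay inside the background range, as did that of *hsp-16.21* (4.68) and that of *C32H11.4* in *daf-2*(e1370) (6.22). *Y39G8B.7* and the small heat shock gene *hsp-16.21* were higher by 3.08 ± 0.70 and 2.80 ± 0.43, with wide spreads in *daf-2*(e1370), where their SDs were 2.27 and 1.43 (n = 5). Of 22548 probe sets 297 differed (limma), 164 higher and 133 lower in e1370, from 244 genes, and after cyclic loess the split was 116 and 155. The arrays did not overlap for 682 probe sets, against the chance share of 0.794%, and 230 of these were among the 297.

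Among yolk protein genes, *vit-1* fell by 2.53 ± 0.49 and *vit-2*, *vit-4*, *vit-5* and *vit-6* had values from -1.06 to -0.88, so that 1 of 5 passed over all probe sets and 5 when adjusted over the list alone (camera adjusted p = 0.000285, adjusted p = 0.34 with an estimated correlation). The means of *vit-4*, *vit-5* and *vit-6* in *daf-2*(m577), 13.91, 13.86 and 13.86, lay close to the highest values on its arrays, 14.08 to 14.23. The sizes of their differences may therefore be limited by the top of the scale. The mean level of the list was 12.16 ± 1.07 in *daf-2*(e1370) and 13.44 ± 0.05 in *daf-2*(m577) (SD, n = 5, exact permutation test, p = 0.00794, adjusted p = 0.0595 over 60 tests), and the difference of -1.28 became -0.85 without replicate 1 of *daf-2*(e1370). Intestinal genes had 4 of 19 lower and none higher, 11 when adjusted over the list alone (camera adjusted p = 7.21e-08, adjusted p = 0.248 with an estimated correlation), among them *pgp-1* (-2.15 ± 0.34) and the proton pump subunit *vha-6* (-1.41 ± 0.34). Among 26 cathepsins and aspartyl proteases *asp-8*, *asp-1* and *cpz-1* fell, by 1.00 to 1.52, and none rose (13 lower and 2 higher when adjusted over the list alone, camera adjusted p = 7.16e-07, adjusted p = 0.225 with an estimated correlation). *acdh-1*, an acyl-CoA dehydrogenase, was lower by -4.42 ± 0.93. Of 59 mitochondrial ribosomal protein genes 6 were higher in e1370, and 37 when adjusted over the list alone (median 0.72, camera adjusted p = 1.75e-23, adjusted p = 0.225 with an estimated correlation), including *mrpl-54* (1.62 ± 0.39) and *mrps-17* (1.59 ± 0.35). *hsp-12.6* (2.55 ± 0.54) and *hsp-12.3* (1.67 ± 0.37) were higher among 10 small heat shock genes, 4 when adjusted over the list alone (camera adjusted p = 0.0075, adjusted p = 0.248 with an estimated correlation). The mean of *hsp-12.6* in *daf-2*(m577), 5.66, and that of *pgp-1* in *daf-2*(e1370), 6.03, lay inside the background range. The spread of *hsp-12.6* in *daf-2*(e1370) was wide, with an SD of 1.63 (n = 5).

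The count of 297 was 30 with the block for the alternative sample names, 91 in the test against a 1.2-fold change, 176 with only these genotypes, 775 without the least typical array of each genotype, 1289 with the oocyte and sperm scores as covariates and 2611 with array quality weights. Leaving out 1 array gave 162, 695 and 166 without replicates 1, 3 and 4 of *daf-2*(e1370), 179, 144, 632, 121 and 124 without replicates 1 to 5 of *daf-2*(m577), and 604 without replicate 2 of *daf-16*(mgDf50); *daf-2*(e1370).

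Without *daf-16*, the 2 *daf-2* alleles differed in 1 probe set of 22548 (limma), 188587_s_at, with 775 probe sets at an unadjusted p under 0.05. It is annotated to 2 genes and was singled out after its values were seen. Its level was 9.43 ± 0.83 in *daf-16*(mgDf50); *daf-2*(e1370) and 6.92 ± 0.13 in *daf-16*(mgDf50); *daf-2*(m577), against 10.88 ± 0.83 and 10.80 ± 0.22 with *daf-16* present (SD, n = 5), a difference between alleles of 2.52 ± 0.36 (adjusted p = 0.0417). The arrays of the 2 genotypes did not overlap for 146 of the 22548 probe sets, which is below the chance share of 0.794%. Among the gene lists, the median was 0.26 for mitochondrial ribosomal protein genes (camera adjusted p = 1.96e-09) and -1.08 for sperm genes (camera adjusted p = 4.61e-15), with no member past the threshold over all probe sets or over the list alone and adjusted p = 0.881 for both with an estimated correlation. Without replicate 5 of *daf-16*(mgDf50); *daf-2*(e1370) these medians were 0.13 and -0.39, and without its replicate 4 the first was 0.39. The mean 3' minus 5' difference was 1.47 ± 0.11 in *daf-16*(mgDf50); *daf-2*(e1370) and 1.87 ± 0.25 in *daf-16*(mgDf50); *daf-2*(m577) (SD, n = 5, exact permutation test, 2-sided, p = 0.00794, adjusted p = 0.0595 over 60 tests).

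The call was lost, leaving a count of 0, after cyclic loess, with only these genotypes, with 1 probe set per gene, in the test against a 1.2-fold change, with the block for the alternative sample names and with the 3' minus 5' difference as a covariate. The count was 3 with the oocyte and sperm scores as covariates or without the least typical array of each genotype, and 99 with array quality weights. It was also 0 without any 1 of 15 arrays, namely replicates 1, 2 and 4 of *daf-2*(e1370), replicates 1 to 5 of *daf-2*(m577), replicates 1, 3 and 4 of *daf-16*(mgDf50); *daf-2*(e1370) and replicates 2 to 5 of *daf-16*(mgDf50); *daf-2*(m577). It was 2 without replicate 2 of *daf-16*(mgDf50); *daf-2*(e1370) and 5 without replicate 1 of *daf-16*(mgDf50); *daf-2*(m577).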

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

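The tests of RNA integrity, hybridisation level, neighbouring genes, control probe sets, left-out arrays, spread and covariates were chosen only after the result was seen, whereas the splits of the arrays were chosen beforehand.

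Other splits of the arrays were counted for each comparison, with the real split among 100. Chance was excluded for the *daf-16* difference over both alleles (1425 calls, 1 split as large, at most 1 call in any other split) and in m577 (404 calls, 1 split as large, highest other 1). Between alleles with *daf-16* (297 calls) 1 split was as large, under the preset limit, but the highest other gave 195. The real count ran from 121 to 695 with 1 array left out, so this share does not by itself exclude chance. For the difference between differences (40 calls) 4 splits were as large, a share just under the preset limit of 0.05, and the highest other gave 1250. With another split so far above the real count, this share does not by itself exclude chance. For the *daf-16* difference in e1370 (987 calls) 5 splits were as large, so chance was not excluded, and the highest other gave 4776. Splits with several times the real count point to a structure of the samples other than genotype. Between alleles without *daf-16* (1 call) 6 splits were as large and the highest other gave 4, so chance was not excluded.

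Arrays of 1 genotype lay apart along oocyte and sperm genes, and the first component of the deviations from genotype means held 47.3% of their variance and had a correlation of size 0.892 with the sperm minus oocyte score over 20 arrays. RNA integrity is argued against as the whole cause, since the 3' minus 5' difference had r = 0.0295 with this score (95% interval -0.458 to 0.503, permutation p = 0.904, adjusted p = 0.904, rho = -0.0782, p = 0.742, r = -0.0525 without the 2 farthest arrays, 2 relations tested). Hybridisation level stays open, since the control level had r = 0.669 (interval 0.278 to 0.870, permutation p = 0.00127, adjusted p = 0.00254, rho = 0.708, p = 0.00067, adjusted p = 0.00134), 0.696 without the 2 farthest arrays and 0.494 without the 3 arrays lowest in sperm genes. Differences in the age of the animals at harvest could also give such a pattern and were not tested. No biological explanation was tested.

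Probe set 188587_s_at was higher in e1370 than in m577 without *daf-16*, and control probe sets of the array for catalase, which are not among the 22548 probe sets, differed in the same direction by 2.08 (3' probe set), 1.63 (middle) and 1.29 (5' probe set). A fault of 1 probe set is argued against by the lowest of these, 1.29, although the control probe sets could share probes with it. Their means in *daf-16*(mgDf50); *daf-2*(m577), 6.25, 6.12 and 5.57, lay inside the background range, so the sizes of their differences are limited by background. A gain or loss of the surrounding region is argued against by the 10 nearest measured genes, whose median difference was 0.12 (range -0.50 to 0.64, none called), and a single array by the lowest difference with 1 array left out, 2.33. Whether the *daf-2* allele or another difference between the strains gave the value stays open.

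The *daf-16* differences were larger in e1370 for 71.7% of the 1425 probe sets called over both alleles, and 69.3% to 73.1% with 1 array left out, but for 39.2% of all 22548 probe sets, so the pattern belongs to the called probe sets. With both the oocyte and sperm scores as covariates the share was 71.6%, but this does not decide on oocyte and sperm content. The 1425 probe sets were called without these scores, and 961 of them were still called with them. The sperm gene mean differed by -1.12 between the m577 genotypes and by -0.14 between the e1370 genotypes. The share with the 3' minus 5' covariate was 73.8%, but this does not decide on RNA integrity. That covariate differed strongly between the m577 genotypes (1.33 ± 0.16 against 1.87 ± 0.25, SD, n = 5) and little between the e1370 genotypes (1.37 ± 0.19 against 1.47 ± 0.11). It thus stands close to the m577 difference itself, and the 1425 probe sets were called without it. For a wider spread of the e1370 arrays, the lower median SD of its genotypes was 0.356 and the higher of those in m577 was 0.321. A wider spread would also enlarge differences over all probe sets, yet their median size was 0.13 in e1370 and 0.20 in m577. Over all probe sets there was thus no excess in e1370 for spread to explain, so these values do not decide on spread. The spread of the called probe sets was not compared, so for them it stays open. Hybridisation level, the *daf-2* allele itself, strain background and the structure shown by the splits also stay open, as untested.

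The *daf-16* difference depended on the allele, by the test of the difference itself, for 40 probe sets. Among the named genes it was positive for *cdr-3* (3.78), *F40G12.5* (2.88), *far-7* (2.82), *dod-3* (2.74), *gst-3* (2.65), *K03D3.2* (2.56), *F53A9.1* (2.49), *cyp-13B1* (2.38), *piit-1* (2.35) and *djr-1.2* (2.35). It was negative for *ilys-5* (-5.24), *C32H11.4* (-4.18), *irg-5* (-3.92), *C17H12.8* (-3.46), *dod-24* (-3.12), *C17H12.6* (-2.47), *W04A4.2* (-2.28), *irg-8* (-2.27), *drd-50* (-2.06) and *fat-7* (-1.91). For *cdr-3*, *F40G12.5* and *djr-1.2* the means of 3 genotypes lay inside the range of the Bacillus controls, so the sizes of these values are limited by background.

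The same test at the preset correlation also set apart 22 of 46 gene lists, and with an estimated correlation it set apart 1, the genes reported elsewhere as lowered in *daf-2* mutants (median -0.77). The medians above 0 were 1.22 for sperm genes (0.52 without replicate 3 of *daf-2*(m577) and 0.55 without replicate 5 of *daf-16*(mgDf50); *daf-2*(e1370)), 0.63 for saposin-like genes, 0.45 for mitochondrial ribosomal proteins, 0.42 for mitochondrial stress genes, 0.26 for genes reported elsewhere as raised in *daf-2* mutants and 0.22 for translation factors. They were 0.21 for histones, 0.20 for insulin-like peptides, 0.18 for respiratory chain genes, 0.18 for cytosolic ribosomal proteins, 0.17 for superoxide dismutases and catalases and 0.04 for glutathione S-transferases. The medians below 0 were -0.71 for yolk proteins, -0.31 for intestinal genes, -0.30 for ATP-binding cassette transporters, -0.22 for UDP-glucuronosyltransferases and -0.21 for lysozymes. They were -0.21 for C-type lectins, -0.18 for beta-oxidation genes, -0.17 for cathepsins and aspartyl proteases and -0.13 for dauer hormone and TGF-beta genes.

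Single arrays stood apart from the other 4 of their genotype in 50 of 416 groups of 5 values, in that the gap to the nearest array exceeded 0.71 of the whole range (Dixon's criterion). Chance gives about 1 in 20 groups, or 20.8 here. Replicate 2 of *daf-16*(mgDf50); *daf-2*(e1370) gave 13 of them: *scl-20* (7.14), *ttr-26* (7.71), *irg-8* (10.97), *dod-3* (9.27), *daf-16* probe set 181992_s_at (6.04), *daf-2* probe set 176986_s_at (5.13), *sgk-1* (7.22), *ins-7* (11.43), *hsp-12.6* (5.36), *sod-5* (7.12), *vit-4* (12.55), *vit-5* (12.55) and *vha-6* (10.23). Replicate 3 of *daf-2*(m577) gave 12: *sod-3* (9.72), *dod-24* (9.01), *col-183* (11.31), *hsp-12.3* (11.10), *F40G12.5* (5.74), *bcf-1* (9.85), *cyp-35A3* (7.21), *spp-13* (6.30), *lbp-7* (7.20), *nhx-2* (4.92), *acdh-1* (6.67) and the sperm gene mean (7.80). Replicate 5 of *daf-16*(mgDf50); *daf-2*(m577) gave 9: *D1086.9* (6.23), *scl-20* (6.95), *K03D3.2* (5.76), *daf-16* probe set 181992_s_at (5.83), *daf-2* probe set 176986_s_at (5.45), *glp-4* (7.07), *hsp-12.6* (5.31), *vit-5* (13.63) and the yolk protein mean (13.26). Replicate 5 of *daf-2*(e1370) gave 4: *hsp-12.3* (10.99), *F40G12.5* (6.47), *sod-5* (7.07) and *acdh-1* (8.57).

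The remaining values that stood apart came from 9 arrays. In *daf-2*(e1370) they were *pgp-5* on replicate 1 (5.96), *daf-16* probe set 175823_s_at on replicate 2 (7.09), *mrps-17* on replicate 3 (9.09) and *asp-8* on replicate 4 (6.41), and in *daf-2*(m577) *glp-4* on replicate 1 (6.08). In *daf-16*(mgDf50); *daf-2*(e1370) they were *nnt-1* (6.55) and the 3' minus 5' difference (1.29) on replicate 4 and *F15B9.6* on replicate 5 (8.45). In *daf-16*(mgDf50); *daf-2*(m577) they were *col-183* (5.94), *asp-8* (7.91) and the 3' minus 5' difference (2.32) on replicate 1 and *cyp-35B1* on replicate 4 (7.16).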

How the results depend on the processing

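The settings with covariates and the one without the least typical array of each genotype (4 arrays left out) were chosen only after the data were seen. None of the 211 calls of named genes reversed under any setting run or without any array. They were chosen on these data for passing the threshold, and many also for arrays without overlap, which makes a reversal unlikely. Of the named calls, 46 of 62 over both alleles, 48 of 57 in e1370, 16 of 35 in m577, 10 of 33 between alleles with *daf-16* and 0 of 1 without it kept their call throughout. For the difference between differences 3 of 23 did, *ilys-5*, *cdr-3* and *djr-1.2*.

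Apart from the blocks, given last, the counts moved by more than 1.5 times under these settings, and the cause was not tested except where stated. Over both alleles, 1425 became 3390 with array quality weights, 649 in the test against a 1.2-fold change, which is stricter by construction, and 643 with the 3' minus 5' covariate. In e1370, 987 became 507 with only the genotypes compared and 616 against a 1.2-fold change. In m577, 404 became 6645 with weights, 780 with only the genotypes compared, 180 against a 1.2-fold change, 58 with the 3' minus 5' covariate and 672 with 4 arrays left out. For the difference between differences, 40 became 1113 with weights, 24 against a 1.2-fold change, 120 with the oocyte and sperm covariates and 16 with the 3' minus 5' covariate. Between alleles with *daf-16*, 297 became 2611 with weights, 176 with only the genotypes compared, 91 against a 1.2-fold change, 1289 with the oocyte and sperm covariates and 775 with 4 arrays left out. Without *daf-16*, 1 became 99 with weights, which kept the probe set called before, and 3 with the oocyte and sperm covariates or 4 arrays left out, which did not. It became 0 after cyclic loess, with only the genotypes compared, with 1 probe set per gene (188587_s_at has no single gene and is not among them), against a 1.2-fold change and with the 3' minus 5' covariate. Calls of gene lists numbered 113 at the preset correlation and 10 with an estimated one, and 79 to 121 under the other settings.

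Without 1 array at a time, the counts ran from 1214 to 1762 over both alleles, 813 to 1245 in e1370, 257 to 527 in m577, 24 to 71 for the difference between differences, 121 to 695 between alleles with *daf-16* and 0 to 5 without it, and list calls from 95 to 121. Medians that reversed were those of C-type lectins in m577 among brighter probe sets (-0.12), mitochondrial ribosomal proteins in m577 with the 3' minus 5' covariate (0.16) and chemoreceptors between alleles with *daf-16* after cyclic loess (0.025), and the cause was not tested.

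For the replicate numbers of the labels, 14 of 30 pairs with a shared number had correlated deviations over 0.1 (median 0.08, range -0.54 to 0.82). Pairs with different numbers were not counted, so this does not decide whether either numbering pairs the arrays. With the replicate block the counts were 1430, 1032, 391, 40, 225 and 3 in the order above, with 113 list calls. For the numbers in the alternative names, 9 of 20 pairs were over 0.1 (range -0.60 to 0.76), and with that block the counts were 699, 709, 105, 6, 30 and 0. The numbers 7 and 8 occurred only on replicates 4 and 5 of *daf-2*(m577), which that block therefore fits alone. Fits of only the genotypes compared gave no value for comparisons of all 4 genotypes, and the oocyte and sperm lists gave none under their own covariates. Differences in probe sets near the background of 4.57, such as those of *daf-2*, are limited by signal, and 79 of 211 called values of named genes rest on at least 1 genotype mean inside the range of the Bacillus controls.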

Other observations

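All tests in this part were chosen only after the data were seen. Besides the fixed lists, 121 families of at least 10 genes that share a symbol were tested in the *daf-16* difference over both alleles and between alleles with *daf-16*, and none of those described passed with an estimated correlation. Of 11 acid phosphatases of the *pho* family 6 fell and none rose with *daf-16* present, 6 and 1 when adjusted over the list alone (median -1.19, camera adjusted p = 3.93e-05, adjusted p = 0.474 with an estimated correlation). Besides *pho-1*, *pho-8* fell by 2.50 ± 0.32, *pho-9* by 1.42 ± 0.28 and *pho-4* by 1.31 ± 0.28 (SE, n = 5 per genotype), and the means of *pho-8* in both genotypes with *daf-16*, 5.70 and 5.81, lay inside the range of the Bacillus controls. Subunits of the vacuolar proton pump (*vha*) had 2 of 18 lower and none higher, 5 lower when adjusted over the list alone (median -0.33, camera adjusted p = 0.00136, adjusted p = 0.988 with an estimated correlation), with *vha-6* at -0.94 ± 0.24 and *vha-1* at -0.46 ± 0.12. Transthyretin-like genes (*ttr*) had 7 of 40 higher and none lower, 8 and 1 when adjusted over the list alone (camera adjusted p = 0.00403, adjusted p = 0.988 with an estimated correlation), and *ttr-23* rose by 2.69 ± 0.32.

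Between alleles with *daf-16*, the 10 RNA polymerase subunit genes named *rpb* had a median of 0.94, with none past the threshold over all probe sets and 8 higher when adjusted over the list alone (camera adjusted p = 1.81e-05, adjusted p = 0.891 with an estimated correlation). *rpb-10* differed by 1.35 ± 0.40 and *rpb-4* by 1.13 ± 0.35 (adjusted p = 0.102 and 0.109). The medians of these families kept their sign when arrays were centred on their medians and after cyclic loess.

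Genes that changed with *daf-16* over both alleles often lay next to each other. Among 17077 genes in chromosome order, 137 adjacent pairs were called in the same direction, against a mean of 40.87 and a highest value of 66 in 10000 shuffles of the calls along each chromosome (permutation p = 1e-04, the smallest that the shuffles can give). Chance placement is therefore argued against. The longest run was of 8 genes on chromosome IV that fell, with differences from -3.22 to -0.42, among them *dod-22* and *dod-17*. Another 5 on chromosome IV fell, with differences from -3.06 to -1.09, *C17H12.8* and *C17H12.6* among them, and 5 on chromosome V, including *D1086.9* and *H39E23.3*, rose by 2.17 to 5.76. These runs were named after their values were seen. Operons, shared regulation and hybridisation between neighbouring copies of a gene were not tested.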
